A study of Mus musculus with 14 samples.

How the data were processed

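RNA from 14 mouse prostate samples was measured on Affymetrix Mouse Genome expression arrays, 1 array per sample. Per the labels' protocols, total RNA was extracted with Trizol and made into biotinylated cRNA for hybridization. The deposited values are log2 expression per probe set, and per the submitters' processing notes the arrays were processed with MAS5. The log transformation and any step that brought the arrays to a common scale are not given in the sources used here. That the values are on a log2 scale was read from the values themselves, which ran from 1.96 to 14.12 with no 0 and with array medians between 5.61 and 5.81. A natural logarithm of this size would lie above what a scanner records. A pseudocount and its alternative had been planned for linear values and did not apply. No further between-array normalization was applied in the main fits.

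The table held 45101 probe sets, of which 64 were controls and were left out. The annotation gave 1 gene symbol for 34958 probe sets and several for 932, while 9211 were not listed in it and stay unnamed here. Probe sets with several symbols were not used. Of the named probe sets, 99.4% had an Entrez identifier present in the gene table used to update symbols, and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean over the 14 arrays, and genes with a mean under the 40th percentile of probe sets (5.19) were left out, which left 13017 genes. Among called genes with several probe sets, the sign of at least 1 other probe set was opposite for 154 of 1918 in bulk PtenApc against bulk Pten and 134 of 1268 in bulk PtenSmad4 against bulk Pten. It was opposite for 99 of 1157 in bulk PtenApc against bulk PtenSmad4 and 194 of 566 in sorted cells against bulk PtenApc. Pten has no named probe set here and was not analysed here, and the same held for Tcf7, Nkx3-1, Ar, Stat1, Isg15, Spp1 and Ly6g of the gene lists. The number of arrays limits the precision of every value.

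Samples were grouped by the titles, genotypes and tissues in the labels. Tests were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method over the 13017 genes with a threshold of 0.05. The bulk genotype comparisons used the 10 bulk arrays with genotype and lobe as terms. Sorted cells were compared with the 3 bulk PtenApc arrays without a lobe term. Lobes were compared with the tumour, taken as arrays of 1 genotype, replicate number and age, as a block. A further fit on the 8 dorsolateral and ventral arrays tested whether their difference was another one in the double deletions than in Pten tumours. The labels do not say which lobes came from the same mouse. Where arrays share an animal, p-values over lobes are too small. The comparisons, alternatives, gene lists and the rule for named genes were fixed before the data were examined.

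The rule named Pten, Apc and Smad4 first, then the 10 largest increases and the 10 largest decreases among genes that passed the test, and up to 4 members of each described list with the smallest p. Predicted genes without a usual name were skipped, which removed 1 decrease each in the comparisons of bulk PtenApc and bulk PtenSmad4 with bulk Pten. Where no gene passed, the 5 with the smallest p were named, and 1 predicted gene was skipped for the anterior lobe. Of 28 gene lists, 27 with at least 3 measured members were tested, and the erythroid list with 1 measured member was not. The lists held 432 genes, of which 349 were tested. One gene was shared by the TGF-beta and YAP target lists and 1 by the YAP target and chemokine lists. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the 27 lists of a comparison.

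The alternatives set beforehand were quantile normalization over the 14 arrays, no filter, a filter at the 60th percentile (6.41), the mean of all probe sets of a gene, each array left out in turn, the tumour as a random block, dorsolateral and ventral arrays alone, and a fit of all 14 arrays. Other alternatives were chosen after seeing the data. These were 1 Pten tumour of the nearest age as the only control, gene lists and the interaction with single arrays left out, gene lists in the fit of all 14 arrays, the shared calls without GFP+ replicate 1, and quantile normalization and single sorted arrays left out for the share of genes above bulk. Every pair of arrays was checked for identical values, and no pair was found to be the same sample entered again.

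The fits were tested on simulated data in which 100 genes were changed by 2-fold and 100 by 4-fold. The share of genes changed by 2-fold that was recovered was 74% for bulk PtenApc against bulk Pten, 80% for bulk PtenSmad4 against bulk Pten and 82% for bulk PtenApc against bulk PtenSmad4. It was 40% for sorted cells against bulk PtenApc, 64% for dorsolateral against ventral, 63% for the anterior lobe and 1% for the interaction. At 4-fold the shares were 91%, 93%, 94%, 73%, 89%, 83% and 51% in the same order. No recovered gene had the wrong sign, and between 1 and 13 unchanged genes were called per simulation. The Wnt target list, with its members raised by 2-fold, was called in each of the 4 simulated main comparisons, and 0 of the 26 other lists were. The simulated genes varied independently of each other, so false list calls where members vary together were not tested.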

Results

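Expression was measured in 14 samples from mouse prostate tumours in which Cre recombinase, driven by a probasin promoter, deleted Pten alone, Pten with Apc, or Pten with Smad4. Pten is a brake on PI3K signalling, Apc on Wnt signalling, and Smad4 carries TGF-beta and BMP signals to the nucleus. Of these, 10 samples were unsorted bulk tumour from single prostate lobes, the anterior, the dorsolateral and the ventral lobe. There were 4 of Pten tumours, dorsolateral and ventral, with replicate 1 at 25.0 weeks and replicate 2 at 19.6 weeks. Another 3 were of PtenApc tumour tissue at 19.6 weeks and 3 of PtenSmad4 tumour tissue at 25.9 weeks. Whether the 3 lobes of a double deletion came from 1 mouse is not in the labels. The double deletions had 1 array each of the anterior, dorsolateral and ventral lobe. The other 4 samples were PtenApc cells sorted for green fluorescence (GFP+), which the reporter turns on in cells with Cre activity, from mice of 22.6, 23.5, 23.5 and 15.2 weeks. Medians per array lay between 5.61 and 5.81 on the log2 scale. The number of arrays limits the precision.

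The first principal component over 13017 genes held 41.1% of the variance and placed the sorted cells (52.5 to 67.1) apart from the bulk tumours (-46.8 to 16.0). The second held 22.2%, and on it GFP+ replicate 1 lay at -44.7 while the other 3 sorted arrays lay between 26.8 and 36.8. That array also had the highest macrophage level of the sorted arrays, a list mean of 10.50 against 5.54, 6.26 and 7.42, and the highest endothelial level, 8.06 against 5.50 to 5.77. The most similar pair of arrays was PtenSmad4 dorsolateral and ventral, whose difference over genes had an SD of 0.233.

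Smad4 had the lowest level in PtenSmad4 tumours, 9.09 (anterior), 9.35 (dorsolateral) and 9.20 (ventral) on the log2 scale, a mean of 9.21 ± 0.13 (SD, n = 3). In Pten tumours it read 11.39 and 11.36 in the dorsolateral and 11.78 and 11.63 in the ventral arrays of replicates 1 and 2, a mean of 11.54 ± 0.20 (SD, n = 4). PtenApc tumours, in which Smad4 was not targeted, lay between them at 10.10, 9.996 and 10.55 in the anterior, dorsolateral and ventral lobe. The 4 sorted PtenApc arrays read 10.10, 10.09, 10.22 and 10.54. The other Smad4 probe sets put sorted cells lower, at means of 9.10 ± 0.03 and 9.39 ± 0.21 (SD, n = 4), against 8.73 ± 0.14 and 9.04 ± 0.07 in PtenSmad4 (n = 3), 10.02 ± 0.33 and 10.12 ± 0.31 in bulk PtenApc (n = 3) and 11.44 ± 0.22 and 11.31 ± 0.20 in Pten tumours (n = 4). Smad4 fell by 2.26 ± 0.13 (SE) in PtenSmad4 against Pten tumours (limma, adjusted p = 0.00078) and by 1.26 ± 0.13 in PtenApc against Pten tumours (limma, adjusted p = 0.0027). PtenApc lay 1.00 ± 0.13 above PtenSmad4 (limma, adjusted p = 0.007).

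Apc read 8.84, 8.81, 8.81 and 8.82 in the Pten arrays, 9.18, 9.10 and 8.95 in the anterior, dorsolateral and ventral PtenApc arrays, and 8.78, 8.66 and 8.70 in the PtenSmad4 arrays. The sorted PtenApc arrays read 8.84, 9.53, 9.26 and 9.08. The probe set was thus not lower where Apc was deleted, and the PtenApc value was 0.21 ± 0.06 (SE) above Pten (limma, adjusted p = 0.0416). Of its 3 other probe sets, 2 had the opposite sign, -0.38 and -0.13, in the same comparison, and the mean of the probe sets was -0.02. The call was lost without any 1 of the 10 bulk arrays (adjusted p 0.052 to 0.18). Against PtenSmad4 the value was 0.36 ± 0.06 (limma, adjusted p = 0.0145), and it was lost without the dorsolateral array of PtenApc (0.055) or of PtenSmad4 (0.062). Whether these probe sets lie in the deleted part of Apc is not given, so they do not check the deletion. Pten was not analysed here, since no named probe set represents it.

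**Figure D1:**
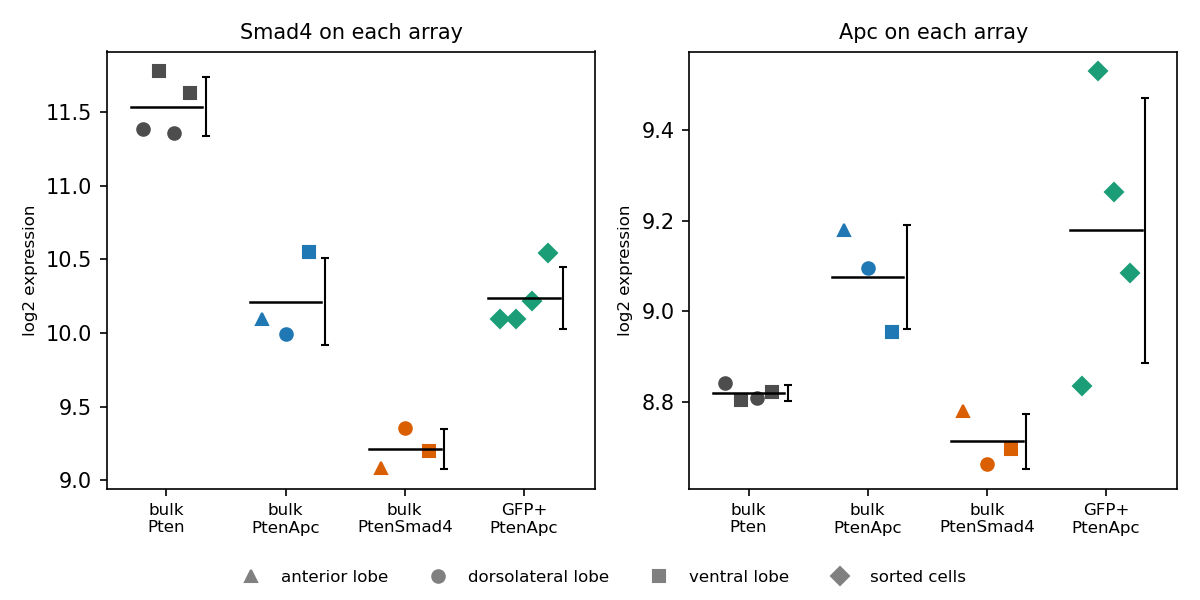
Log2 expression of Smad4 (left) and Apc (right) on each of the 14 arrays by group, with the group mean as a line, the SD as a bar and the lobe as the marker shape. The 3 PtenSmad4 arrays read 9.09 to 9.35 for Smad4, below every other array, while the Apc probe set was not lower in PtenApc arrays.

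The comparison of PtenApc with Pten tumours asks which transcripts differ when Apc is deleted along with Pten. Values are log2 fold changes ± SE from 3 PtenApc and 4 Pten arrays with the lobe in the fit. The largest increases were led by Rptn (6.99 ± 0.67), of the cornifying epidermis like Calm4 (5.55 ± 0.82), and included the wound keratin Krt6b (6.87 ± 0.50), Prr9 (6.57 ± 0.31), the hair keratin Krt33a (6.09 ± 0.80) and the metallothionein Mt4 (5.87 ± 0.70). Mmp12 (6.85 ± 0.62) and Mmp13 (6.12 ± 0.62), both secreted proteases, the lipase Pnliprp2 (6.48 ± 0.81) and the Wnt antagonist Apcdd1 (5.46 ± 0.64) completed the 10 largest. The largest decreases were those of Apof (-6.32 ± 0.54), Spink1 (-5.37 ± 1.47), Egf (-5.24 ± 0.67), Elapor1 (-5.07 ± 0.52) and Anxa13 (-5.03 ± 0.75). They went on with Adh6a (-4.96 ± 0.69), Cdcp3 (-4.49 ± 0.80), Azgp1 (-4.38 ± 0.65), Slc9a2 (-4.30 ± 0.67) and Slc26a4 (-4.20 ± 0.56).

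With limma, 4094 of 13017 genes changed, 1871 higher and 2223 lower, and 907 of the higher and 434 of the lower ones changed by at least 2-fold. Without 1 array the count ranged from 1885 to 4299, with 1885 without PtenApc dorsolateral and 2683 without PtenApc ventral. It was 1445 in a fit of all 14 arrays, and 722 with Pten replicate 2, of the same age as the PtenApc arrays, as the only control. That control ended the calls of Krt33a (adjusted p = 0.05), Calm4 (0.056), Spink1 (0.11), Anxa13 (0.055) and Cdcp3 (0.056). Spink1 (adjusted p = 0.032) was also lost without Pten ventral replicate 1 (0.079), Pten dorsolateral replicate 2 (0.055), Pten ventral replicate 2 (0.079) or PtenApc ventral (0.11). The p-values over lobes are too small where arrays share an animal, and the labels do not name mice, so genotype, tumour and, in part, age cannot be separated.

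Wnt targets rose together. Of 17 measured members 13 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 1.80. Axin2 (2.99 ± 0.29), Nkd1 (4.66 ± 0.53) and Nkd2 (1.49 ± 0.17), feedback inhibitors of the pathway, were among them. The list passed limma's camera test (adjusted p = 6.8e-08, and adjusted p = 0.247 with an estimated correlation). Of 18 TGF-beta and BMP targets 12 rose and 1 fell (14 and 1 adjusted over the list alone), median 0.71, adjusted p = 1.3e-06 (adjusted p = 0.247 with an estimated correlation), in a comparison where endothelial, fibroblast and macrophage genes were higher as well (medians 1.27, 1.16 and 1.42). The BMP-induced repressors Id3 (2.67 ± 0.17) and Id1 (2.08 ± 0.14) led, with the cell cycle inhibitor Cdkn1a (1.35 ± 0.16). Of 12 YAP targets 7 rose and 0 fell (9 and 0 adjusted over the list alone), median 0.80, adjusted p = 0.000212 (adjusted p = 0.247 with an estimated correlation), with Fstl1 (1.34 ± 0.19) and Axl (0.92 ± 0.22) as examples.

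The squamous list had 18 of 22 members higher and 0 lower (21 and 0 adjusted over the list alone), with a median of 2.16. The squamous mean was 9.69 in the dorsolateral and 8.75 in the ventral PtenApc array. In the anterior one it was 6.71, near the 6.01 to 6.45 of the Pten arrays, so the rise was mainly dorsolateral and ventral. Krt13 (4.39 ± 0.48), Dmkn (4.23 ± 0.47) and the envelope protein Ivl (2.68 ± 0.33) rose with Krt6b. The camera test gave an adjusted p = 1.7e-10, and an adjusted p = 0.247 with an estimated correlation. Of 11 basal genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), namely Lamb3 (1.88 ± 0.26), Krt14 (2.24 ± 0.39) and Krt5 (1.37 ± 0.36), while Trp63 read 1.07 ± 0.41 (limma, adjusted p = 0.085). The basal list had a median of 0.72 and an adjusted p = 0.00199 (adjusted p = 0.337 with an estimated correlation). Its mean was 9.26 in the dorsolateral and 9.16 in the ventral PtenApc array but 7.74 in the anterior one, below the 7.86 to 8.66 of the Pten arrays.

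Luminal and androgen-responsive genes fell. Of 12 luminal genes 10 fell and 0 rose (10 and 0 adjusted over the list alone), median -0.76, adjusted p = 9.2e-05 (adjusted p = 0.371 with an estimated correlation). Foxa1 (-1.26 ± 0.13), a partner of the androgen receptor, and the adhesion genes Epcam (-1.30 ± 0.16) and Cldn3 (-1.60 ± 0.21) were among them. Leukocyte, endothelial and fibroblast lists were higher in the same comparison. The luminal mean was 10.94 to 11.63 on bulk PtenApc and 12.05 to 12.16 on Pten arrays, but 11.44, 12.02, 12.08 and 12.03 on the sorted PtenApc arrays. A lower share of epithelial cells in bulk PtenApc was not separated from a fall within them. Of 16 androgen-responsive genes 8 fell and 0 rose (9 and 0 adjusted over the list alone), median -1.05, adjusted p = 0.0035 (adjusted p = 0.247 with an estimated correlation). Examples were the prostate homeobox gene Hoxb13 (-3.38 ± 0.28), Spdef (-1.89 ± 0.21) and Mme (-3.86 ± 0.49). Of 10 progenitor-like luminal genes 2 fell, Sox9 (-1.15 ± 0.27) and Ppp1r1b (-2.14 ± 0.65, lost in 9 of the 10 fits without 1 array). That list did not pass (adjusted p = 0.909), and its median of 0.17 and mean of 0.03 had the opposite sign to the test. The neuroendocrine list (median 0.72, 2 of 5 higher, adjusted p = 0.15) and the mucin list (median 0.34, 1 higher and 2 lower of 13, adjusted p = 0.619) did not pass.

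The lists of leukocyte markers were higher. Of 14 neutrophil genes 10 rose and 0 fell (13 and 0 adjusted over the list alone), median 2.01, adjusted p = 4.2e-07 (adjusted p = 0.247 with an estimated correlation), with Mmp9 (2.78 ± 0.35) and Clec4e (4.20 ± 0.59). Of 17 macrophage genes 13 rose and 0 fell (13 and 0 adjusted over the list alone), median 1.42, adjusted p = 5.0e-06 (adjusted p = 0.371 with an estimated correlation), with Lyz2 (2.39 ± 0.28) and Cybb (2.51 ± 0.30). Of 9 B and plasma cell genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), median 1.12, adjusted p = 0.00038 (adjusted p = 0.247 with an estimated correlation), with Mzb1 (3.18 ± 0.24) and Ms4a1 (2.61 ± 0.22). Of 11 T and NK cell genes 3 rose and 0 fell (5 and 0 adjusted over the list alone), median 0.20, adjusted p = 0.0274 (adjusted p = 0.558 with an estimated correlation). Of 24 chemokine and cytokine genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), median 0.41, adjusted p = 0.00353 (adjusted p = 0.371 with an estimated correlation), and the anterior (8.46) and ventral PtenApc means (8.32) lay within the 7.56 to 8.48 of the Pten arrays.

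Endothelial, fibroblast and transition genes were higher too. Each of 13 endothelial genes rose (13 and 0 adjusted over the list alone), median 1.27, adjusted p = 9.5e-08 (adjusted p = 0.247 with an estimated correlation), with Kdr (1.07 ± 0.14) and Pecam1 (1.35 ± 0.20). Of 15 fibroblast genes 10 rose and 0 fell (10 and 0 adjusted over the list alone), median 1.16, adjusted p = 5.0e-06 (adjusted p = 0.247 with an estimated correlation), with Pdgfrb (2.63 ± 0.32) and Col1a1 (2.10 ± 0.34). Of 11 genes of the epithelial-mesenchymal transition list 9 rose and 0 fell (10 and 0 adjusted over the list alone), median 1.42, adjusted p = 5.0e-06 (adjusted p = 0.247 with an estimated correlation), with Fn1 (1.89 ± 0.21), Vim (2.11 ± 0.32) and Zeb2 (1.80 ± 0.30), which fibroblasts or leukocytes also express. The lists of smooth muscle (median 0.10, 0 of 12 called, adjusted p = 0.497), skeletal muscle (median 1.75, 0 of 6 called, adjusted p = 0.0615), adipocyte (median 1.78, 1 of 3 higher, adjusted p = 0.231) and urothelium genes (median 0.12, 0 of 5 called, adjusted p = 0.48) did not pass. The skeletal muscle mean was 10.22 in the dorsolateral and 8.12 in the ventral PtenApc array and 5.35 in the anterior one, and 9.10 in Pten dorsolateral replicate 1 against 5.88 to 6.56 in the other Pten arrays.

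Interferon-stimulated genes were lower. Of 14 members 11 fell and 0 rose (12 and 0 adjusted over the list alone), median -1.81, adjusted p = 8.5e-05 (adjusted p = 0.371 with an estimated correlation). Among them were the antiviral genes Ifit1 (-2.52 ± 0.31), Ifit3 (-2.86 ± 0.36), Oasl2 (-1.88 ± 0.26) and Xaf1 (-1.50 ± 0.24). Of 15 antigen presentation genes 6 fell and 1 rose (median -0.24, adjusted p = 0.497), with H2-K1 (-0.59 ± 0.10) among those that fell. Proliferation genes had a median of 0.26, with 1 of 23 higher and 1 lower (0 and 1 adjusted over the list alone), and passed (adjusted p = 0.0198, and adjusted p = 0.653 with an estimated correlation). Of those, Mcm3 read 0.59 ± 0.16, and Tpx2 -0.49 ± 0.10 while another probe set read 0.64. Of 19 immediate early genes 4 rose and 2 fell (median 0.47, adjusted p = 0.104). The seminal vesicle genes had a median of 3.30 with 0 of 4 called (3 higher adjusted over the list alone), and passed (adjusted p = 0.0482, and adjusted p = 0.459 with an estimated correlation). The mean of these seminal vesicle genes, whose organ adjoins the anterior prostate, was 11.37 in the anterior, 11.54 in the dorsolateral and 4.56 in the ventral PtenApc array, against 6.94, 3.75, 6.74 and 3.62 in the Pten arrays.

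Of these lists, 18 of 27 passed, and the calls of 4 depended on single arrays. The T and NK list was lost without Pten dorsolateral replicate 1 (adjusted p = 0.062), PtenApc dorsolateral (0.24) or PtenApc ventral (0.059), and the chemokine list without PtenApc dorsolateral (0.05). The proliferation list was lost without Pten dorsolateral replicate 1 (0.081), PtenApc dorsolateral (0.14) or either anterior array (0.11). The seminal vesicle list was lost without any 1 Pten array, PtenApc dorsolateral or either anterior array (0.057 to 0.2). Without PtenApc ventral, the medians of the proliferation, seminal vesicle and chemokine lists were 0.62, 5.40 and 0.75. Of 80 list members named by the rule that passed limma's test, 56 passed in each of the 10 fits without 1 array, while 19 were lost without PtenApc dorsolateral, 13 without PtenApc ventral and 2 to 9 without each of the others. Of the examples above, Axl, Krt5, Sox9, Mcm3, Ppp1r1b and Tpx2 were among the 24 lost in at least 1 such fit (adjusted p up to 0.218).

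**Figure D2:**
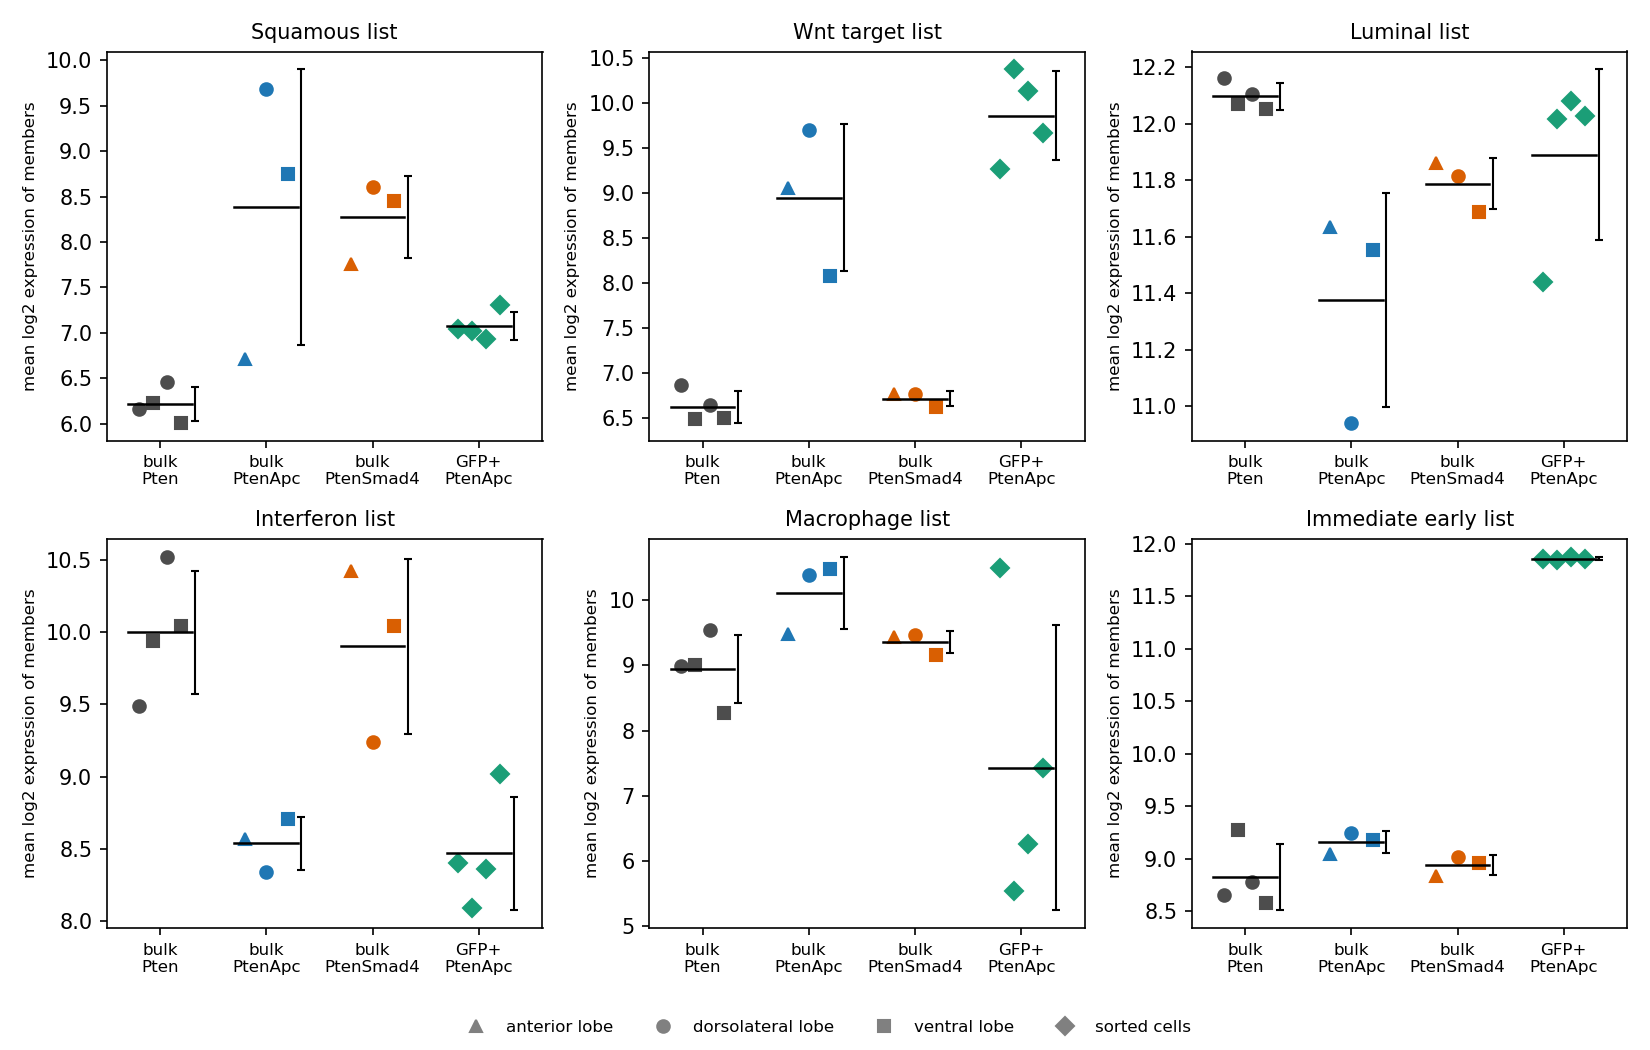
Mean log2 expression of 6 gene lists on each of the 14 arrays by group, with the group mean as a line and the SD as a bar. Wnt targets lay at 8.08 to 9.70 in bulk PtenApc arrays and 9.27 to 10.38 in sorted cells, above the 6.49 to 6.87 of Pten arrays, and immediate early genes lay at 11.84 to 11.87 in sorted cells.

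The comparison of PtenSmad4 with Pten tumours asks the same of Smad4, again as log2 fold changes ± SE from 3 and 4 arrays. The largest increases included the keratins Krt13 (5.04 ± 0.48), Krt6b (4.93 ± 0.50) and Krt10 (4.83 ± 0.43), Calml3 (5.88 ± 0.62), Crabp2 (4.48 ± 0.35), Dapl1 (4.43 ± 0.58) and Dmkn (4.37 ± 0.47). The others of the 10 largest increases were Sptssb (6.36 ± 0.42), a subunit of the enzyme that starts sphingolipid synthesis, the water channel Aqp4 (5.59 ± 0.66) and the platelet chemokine Ppbp (4.88 ± 0.37). The largest decreases were Spink1 (-5.86 ± 1.47), the anion exchanger Slc26a4 (-5.58 ± 0.56), Apof (-5.56 ± 0.54), Egf (-4.67 ± 0.67) and Slc9a2 (-4.64 ± 0.67). Probasin, Pbsn (-4.48 ± 1.01), a secretory protein of the prostate, Saa1 (-4.41 ± 1.02), B4galnt2 (-4.39 ± 0.48), Azgp1 (-4.32 ± 0.65) and Lrrc31 (-4.28 ± 0.59) followed.

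With limma, 2518 genes changed, 1310 higher and 1208 lower, of which 409 and 315 changed by at least 2-fold. Without 1 array the count ranged from 306 to 2575. It was 1369 without Pten dorsolateral replicate 1, 1042 without Pten ventral replicate 1, 1189 without Pten ventral replicate 2, 1484 without PtenSmad4 dorsolateral and 306 without PtenSmad4 ventral. It was 837 in a fit of all 14 arrays, and 526 with Pten replicate 1, the nearer in age, as the only control. That control ended the calls of Dapl1, Spink1, Egf, Slc9a2, Pbsn, Saa1, Azgp1 and Lrrc31. The p-values over lobes are again too small where arrays share an animal, which the labels do not name.

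Single arrays also decided 3 of the decreases. Spink1 (adjusted p = 0.0357) was lost without Pten ventral replicate 1 (0.09), Pten dorsolateral replicate 2 (0.059), Pten ventral replicate 2 (0.09), PtenApc ventral (0.05), PtenSmad4 dorsolateral (0.1) or PtenSmad4 ventral (0.21). Pbsn was lost without Pten dorsolateral replicate 1 (0.053), Pten ventral replicate 1 (0.07), Pten ventral replicate 2 (0.072), PtenSmad4 dorsolateral (0.1) or PtenSmad4 ventral (0.16). Saa1 was lost without Pten ventral replicate 1 (0.071), Pten dorsolateral replicate 2 (0.057), Pten ventral replicate 2 (0.072) or PtenSmad4 ventral (0.18).

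The squamous list had 15 of 22 members higher and 0 lower (16 and 0 adjusted over the list alone), median 2.68, adjusted p = 2.1e-09 (adjusted p = 0.531 with an estimated correlation). Of 11 basal genes 7 rose and 0 fell (9 and 0 adjusted over the list alone), median 1.84, adjusted p = 4.4e-05 (adjusted p = 0.531 with an estimated correlation). Krt5 (3.82 ± 0.36), Krt14 (4.02 ± 0.39) and their regulator Trp63 (2.87 ± 0.41) were among these. Of 12 luminal genes 4 fell and 0 rose (5 and 0 adjusted over the list alone), median -0.37, adjusted p = 0.00328 (adjusted p = 0.785 with an estimated correlation), with Cldn3 (-1.12 ± 0.21) and Foxa1 (-0.60 ± 0.13). Of 16 androgen-responsive genes 9 fell and 1 rose (10 and 3 adjusted over the list alone), median -1.08, adjusted p = 0.00328 (adjusted p = 0.531 with an estimated correlation). Hoxb13 (-2.90 ± 0.28), the steroid-induced Fkbp5 (-1.97 ± 0.24) and Mme (-3.40 ± 0.49) fell. The progenitor-like luminal list did not pass (2 higher and 3 lower of 10, adjusted p = 0.544), and its median of -0.26 and mean of 0.02 differed in sign. Aldh1a1 of that list fell by 3.63 ± 0.43.

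Wnt targets did not pass as a list (2 higher and 2 lower of 17, median 0.01, adjusted p = 0.561). Nkd2 (1.24 ± 0.17) and Ccnd1 (1.23 ± 0.34) rose, and the inhibitor Rnf43 (-1.08 ± 0.30) and the Wnt-induced factor Sp5 (-1.29 ± 0.36) fell. Of 18 TGF-beta and BMP targets 7 rose and 0 fell (8 and 0 adjusted over the list alone), median 0.48, adjusted p = 0.00328 (adjusted p = 0.531 with an estimated correlation). Those with the smallest p were Id4 (1.83 ± 0.26), Cdkn1a (0.97 ± 0.16), Skil (0.79 ± 0.15), which represses Smad signalling, and Ltbp3 (1.18 ± 0.22). The endothelial, macrophage and neutrophil lists were called higher in this comparison as well. YAP targets had 4 of 12 higher and 0 lower (6 and 0 adjusted over the list alone), median 0.38, adjusted p = 0.0455 (adjusted p = 0.785 with an estimated correlation). Proliferation genes were higher, 10 of 23 with 1 lower (13 and 1 adjusted over the list alone), median 0.69, adjusted p = 4.4e-05 (adjusted p = 0.785 with an estimated correlation). The list mean was 8.01 in the dorsolateral and 8.14 in the ventral PtenSmad4 array, while 7.36 in the anterior one lay within the 7.09 to 7.47 of the Pten arrays. The replication licensing genes Mcm4 (0.87 ± 0.13), Mcm3 (0.88 ± 0.16) and Mcm6 (0.73 ± 0.13) were among them, and Tpx2 read -0.41 ± 0.10 while another probe set read 0.77.

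Of 14 neutrophil genes 1 rose (0 adjusted over the list alone), median 0.83, adjusted p = 0.0276 (adjusted p = 0.785 with an estimated correlation), and of 17 macrophage genes 2 rose, Cybb (1.95 ± 0.30) and Ms4a7 (1.21 ± 0.30), median 0.63, adjusted p = 0.0268 (adjusted p = 0.851 with an estimated correlation). The macrophage means of the PtenSmad4 arrays, 9.16 to 9.47, lay within the 8.27 to 9.54 of the Pten arrays. None of 13 endothelial genes passed limma's test singly, and the list, median 0.47, did (adjusted p = 0.00328, and adjusted p = 0.785 with an estimated correlation). Of 11 epithelial-mesenchymal transition genes 4 rose (4 adjusted over the list alone), median 0.56, adjusted p = 0.0276 (adjusted p = 0.785 with an estimated correlation), with Snai2 (2.20 ± 0.25) and Fn1 (1.13 ± 0.21). The fibroblast (median 0.58, 5 higher and 1 lower of 15, adjusted p = 0.0872), smooth muscle (median -0.48, adjusted p = 0.162), B and plasma cell (median 0.26, adjusted p = 0.544), interferon (median -0.17, 0 of 14 called, adjusted p = 0.465) and seminal vesicle lists (median -2.82, adjusted p = 0.126) did not pass. Medians and tests differed in sign from means or from each other for the T and NK (median -0.03, mean 0.12, test up), urothelium (-0.05, 0.56, up) and antigen presentation lists (-0.07, 0.14, down), none of which passed.

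In total 11 of 27 lists passed, and 4 of these calls depended on single arrays. The YAP list was lost without Pten dorsolateral replicate 1 (adjusted p = 0.088), Pten ventral replicate 2 (0.05), PtenApc anterior (0.066), PtenApc dorsolateral (0.067) or any 1 PtenSmad4 array (0.057 to 0.073). The neutrophil list was lost without Pten dorsolateral replicate 1 (0.088), Pten ventral replicate 2 (0.05) or PtenSmad4 dorsolateral (0.077). The macrophage list was lost without Pten dorsolateral replicate 1 (0.067), Pten ventral replicate 2 (0.05), PtenApc anterior (0.19) or PtenSmad4 anterior (0.19). The transition list was lost without Pten ventral replicate 2 (0.069) or either anterior array (0.17). The TGF-beta median was 0.73 without PtenSmad4 dorsolateral, and the proliferation median 0.40 without PtenSmad4 ventral. The neutrophil, macrophage and endothelial calls were also lost in the fit of all 14 arrays. Of 60 list members named by the rule that passed limma's test, 46 were lost without PtenSmad4 ventral (adjusted p up to 0.262). Those that passed in each of the 10 fits were 14, and they included Krt5, Krt14, Krt13, Krt6b, Krt10, Hoxb13, Fkbp5, Mme, Aldh1a1, Cdkn1a and Snai2.

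The comparison of PtenApc with PtenSmad4 tumours asks how the second deletions differ, in log2 fold changes ± SE from 3 arrays each. The largest differences upward in PtenApc tumours included the Wnt antagonists Wif1 (6.96 ± 0.86) and Apcdd1 (4.99 ± 0.64), with Prr9 (6.75 ± 0.31), Mt4 (5.76 ± 0.70), the hair keratin Krt33a (5.06 ± 0.80) and Pnliprp2 (6.14 ± 0.81). The other 4 of the 10 largest increases were seminal vesicle genes, Svs5 (6.68 ± 1.31), Pate4 (6.18 ± 1.49), Svs4 (5.90 ± 1.12) and Svs2 (5.59 ± 1.45). Lower in PtenApc tumours were Tfcp2l1 (-3.80 ± 0.76), Bbox1 (-3.62 ± 0.51), Car12 (-3.51 ± 0.86), Cyp2f2 (-3.50 ± 0.97), Aldh3a1 (-3.49 ± 0.19) and Rttn (-3.46 ± 0.16). H3f3b (-3.18 ± 0.19), Fgfbp1 (-3.07 ± 0.54), Ugt2b34 (-3.02 ± 0.68) and Rhov (-3.01 ± 0.34) completed the 10.

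With limma, 2489 genes differed, 1041 higher and 1448 lower, of which 466 and 234 differed by at least 2-fold. Without 1 array the count ranged from 675 to 2257, with 1573 without Pten ventral replicate 1, 859 without PtenApc dorsolateral, 675 without PtenSmad4 dorsolateral and 759 without PtenSmad4 ventral. In a fit of all 14 arrays it was 608, and Svs5, Pate4, Svs4 and Svs2 were not called. Each double deletion has 1 replicate number and 1 age in the labels. The ages differ, and p-values over lobes are too small where arrays share an animal.

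Several of the named genes rested on single arrays. Cyp2f2 was lost without any 1 array but PtenApc ventral (adjusted p 0.065 to 0.16), and Pate4 and Svs2 without any 1 but PtenApc ventral and PtenSmad4 ventral (0.052 to 0.14). Svs5 was lost without PtenApc dorsolateral (0.073), PtenSmad4 dorsolateral (0.079) or either anterior array (0.056). Tfcp2l1 (0.053 to 0.076) and Ugt2b34 (0.053 to 0.1) were lost without any 1 of PtenApc anterior, PtenApc dorsolateral and the 3 PtenSmad4 arrays. Car12 was lost without any 1 of these or the Pten arrays of replicate 1 (0.054 to 0.12). Krt33a (0.051) and Fgfbp1 (0.063) were lost without PtenSmad4 dorsolateral.

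Wnt targets were higher in PtenApc tumours, 10 of 17 with 1 lower (11 and 1 adjusted over the list alone), median 1.94, adjusted p = 4.9e-07 (adjusted p = 0.541 with an estimated correlation). Axin2 (3.02 ± 0.29), Nkd1 (4.95 ± 0.53) and Znrf3 (2.06 ± 0.25) were among them. Of 18 TGF-beta and BMP targets 4 were higher and 1 lower (4 and 1 adjusted over the list alone), median 0.13, adjusted p = 0.0247 (adjusted p = 0.541 with an estimated correlation). Id3 (2.82 ± 0.17), Id1 (2.18 ± 0.14) and the receptor decoy Bambi (2.16 ± 0.43) were higher and Id4 (-1.61 ± 0.26) lower. Of 11 basal genes 5 were lower and 0 higher (6 and 1 adjusted over the list alone), among them Krt5 (-2.44 ± 0.36), Col17a1 (-2.22 ± 0.40) and Trp63 (-1.81 ± 0.41), and the list, median -1.61, did not pass (adjusted p = 0.0516). Squamous genes split, 3 higher such as Lce3c (2.18 ± 0.47) and Tgm3 (1.65 ± 0.39) and 3 lower such as Krt10 (-2.70 ± 0.43) and Dsc3 (-2.56 ± 0.63), with a median of 0.01 and an adjusted p = 0.383. Luminal genes were lower, 2 of 12 (3 adjusted over the list alone), median -0.36, adjusted p = 0.0252 (adjusted p = 0.611 with an estimated correlation), with Epcam (-0.87 ± 0.16). The YAP (median 0.23, adjusted p = 0.0516) and androgen lists (median -0.14, adjusted p = 0.865) did not pass. The progenitor-like luminal list (median -0.63, mean 0.01, test up, adjusted p = 0.78) did not pass either, while its member Aldh1a1 was higher by 4.55 ± 0.43.

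Interferon-stimulated genes were lower in PtenApc tumours here as well, 9 of 14 with 0 higher (10 and 0 adjusted over the list alone), median -1.60, adjusted p = 0.000186 (adjusted p = 0.556 with an estimated correlation), with Ifit1 (-2.18 ± 0.31) and Oasl2 (-1.78 ± 0.26). Proliferation genes were lower, 2 of 23 (1 adjusted over the list alone), median -0.33, adjusted p = 0.0175 (adjusted p = 0.689 with an estimated correlation). Neutrophil genes were higher, 5 of 14 (5 adjusted over the list alone), median 1.40, adjusted p = 5.5e-05 (adjusted p = 0.541 with an estimated correlation), with Mmp8 (2.62 ± 0.40), and seminal vesicle genes, 4 of 4, median 6.04, adjusted p = 0.002 (adjusted p = 0.541 with an estimated correlation). Fibroblast genes were higher, 2 of 15, median 0.76, adjusted p = 0.000682 (adjusted p = 0.541 with an estimated correlation), and endothelial genes, 5 of 13 (10 adjusted over the list alone), median 0.70, adjusted p = 2.3e-05 (adjusted p = 0.541 with an estimated correlation). B and plasma cell genes were higher, 4 of 9 (7 adjusted over the list alone), median 1.32, adjusted p = 8.5e-05 (adjusted p = 0.287 with an estimated correlation), with Mzb1 (3.03 ± 0.24).

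Macrophage genes, 2 of 17, had a median of 0.66 (adjusted p = 0.000186, and adjusted p = 0.556 with an estimated correlation), skeletal muscle genes, 0 of 6, one of 2.17 (adjusted p = 0.0122, and adjusted p = 0.556 with an estimated correlation), chemokines, 3 of 24 (1 adjusted over the list alone), one of 0.48 (adjusted p = 0.0145, and adjusted p = 0.556 with an estimated correlation), and transition genes, 4 higher and 1 lower of 11 (6 and 1 adjusted over the list alone), one of 0.76 (adjusted p = 0.00807, and adjusted p = 0.556 with an estimated correlation). The T and NK list, 1 of 11, median 0.14 (adjusted p = 0.035, and adjusted p = 0.611 with an estimated correlation), and the smooth muscle list, 2 of 12, median 0.72 (adjusted p = 0.0263, and adjusted p = 0.639 with an estimated correlation), passed as well. The antigen presentation list, 3 of 15 lower, median -0.13, did not pass (adjusted p = 0.37), nor did the urothelium list (median 0.18, mean -0.46, test down, adjusted p = 0.882).

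In this comparison 16 of 27 lists passed. Without PtenApc dorsolateral the luminal (adjusted p = 0.16), T and NK (0.21), smooth muscle (0.29), skeletal muscle (0.064) and chemokine calls (0.077) were lost. Without PtenSmad4 dorsolateral the luminal (0.097), T and NK (0.094), smooth muscle (0.18), skeletal muscle (0.06) and TGF-beta calls (0.07) were. Without PtenApc ventral the T and NK (0.08), smooth muscle (0.075), TGF-beta (0.11) and proliferation calls (0.49) were lost, the macrophage median was 0.40 and the B and plasma cell median 0.82. Without PtenSmad4 ventral the T and NK (0.12), smooth muscle (0.071) and proliferation calls (0.24) were lost. Without either anterior array the medians of TGF-beta targets, proliferation, macrophage, T and NK and smooth muscle genes were 0.27, -0.65, 1.03, 0.22 and 1.15. The macrophage and chemokine calls were lost in the fit of all 14 arrays. Of 70 list members named by the rule that passed limma's test, 23 passed in each of the 10 fits without 1 array, Axin2, Nkd1, Znrf3, Wif1, Id3, Id1, Krt5, Krt10, Aldh1a1, Mzb1, Ifit1 and Oasl2 among them. Losses were most frequent without PtenSmad4 dorsolateral (39), PtenSmad4 ventral (39) and PtenApc dorsolateral (35), with adjusted p up to 0.162.

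Both double deletions were compared with the same 4 Pten arrays, so their changes are correlated in part by construction. Over 13017 genes, which are not independent replicates, the log2 fold changes had a correlation of 0.61 and a covariance of 0.277, and 70.0% of genes had the same sign. Simulated unchanged groups against the same controls gave a correlation of 0.50, a covariance of 0.028 and 66.7%. With each deletion compared with another Pten replicate, the correlation was 0.60 or 0.53 and the covariance 0.276 or 0.254. Krt6b, Krt13 and Dmkn rose and Apof, Egf and Slc26a4 fell in both comparisons. In all, 571 genes were called higher in both (188 if the calls were independent) and 778 lower in both (206), and 50 changed in opposite directions (397). With separate controls, PtenApc against Pten replicate 1 and PtenSmad4 against replicate 2 called 20 genes higher in both and 6 lower in both (2.12 and 0.494 if independent). With the replicates exchanged the counts were 73 and 65 (9.05 and 5.72). Both fits share double-deletion arrays, which alone can give an excess over independence.

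**Figure D3:**
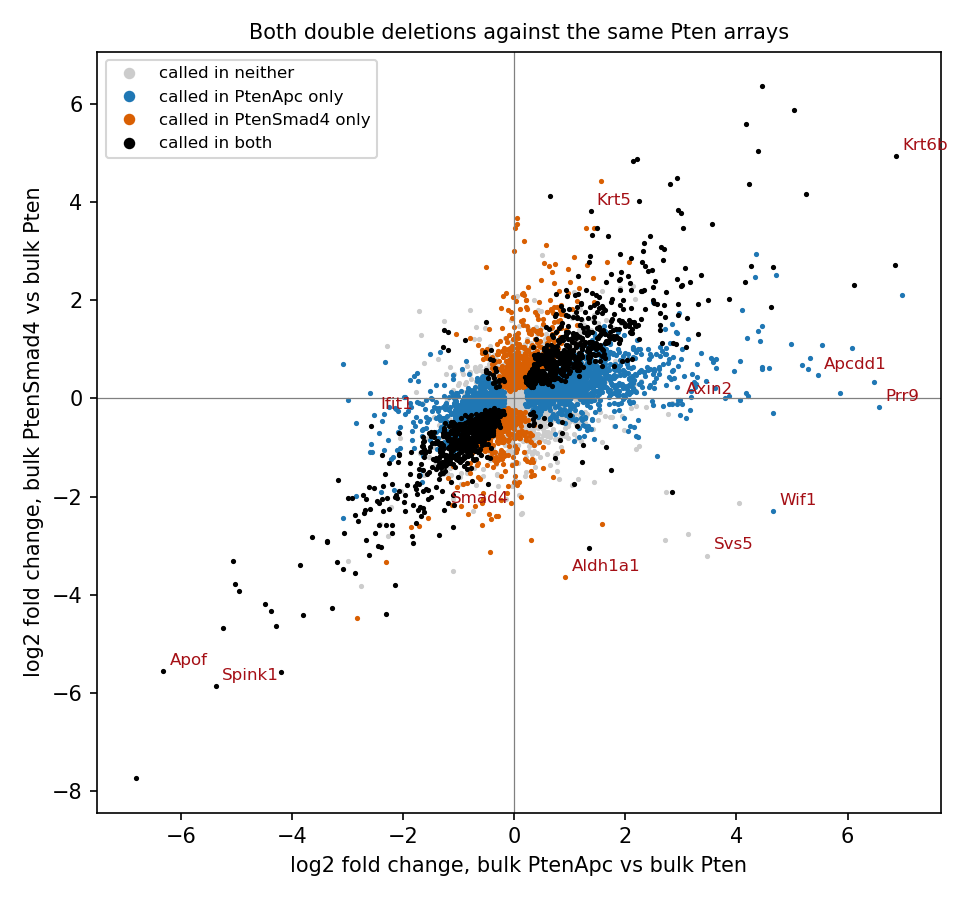
Log2 fold change of each gene against Pten tumours, PtenApc on the horizontal and PtenSmad4 on the vertical axis, coloured by the comparison in which the gene was called, with named genes labelled. Krt6b lies high on both axes (6.87 and 4.93), while Axin2 (2.99) lies high in PtenApc.

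The comparison of sorted GFP+ PtenApc cells with bulk PtenApc tumours asks which transcripts belong to the Cre-positive cells. Values are log2 fold changes ± SE from 4 sorted and 3 bulk arrays. The largest increases in sorted cells included the immediate early genes Fosb (6.86 ± 0.27), Fosl1 (4.21 ± 0.35), Gem (4.99 ± 0.59), Dusp10 (3.75 ± 0.35) and the heat shock gene Hspa1a (3.70 ± 0.46). The cytokines Il6 (5.78 ± 0.71), Csf2 (4.15 ± 0.53) and Lif (3.88 ± 0.41) were higher, as were Coch (4.39 ± 0.65) and Pik3cd (3.83 ± 0.17, with -1.10 for another probe set). The largest decreases included the keratin gene Krt6b (-5.31 ± 1.03), Calm4 (-4.40 ± 1.06), Lce3a (-3.91 ± 0.88), Lce3f (-3.84 ± 0.84) and Krtap13-1 (-3.82 ± 0.88). The leukocyte genes Mmp12 (-4.99 ± 1.13), Ms4a4b (-3.77 ± 0.36) and Itgax (-3.59 ± 0.74), the endothelial receptor Aplnr (-4.51 ± 0.71) and Lpl (-4.45 ± 0.95) were lower as well.

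With limma, 1068 genes differed, 564 higher and 504 lower, of which 294 and 317 by at least 2-fold. Without GFP+ replicate 1, the array with high leukocyte and endothelial levels, 3351 differed, 1861 higher and 1490 lower, and all of the 1068 were among them in the same direction. Without other single arrays the count was 635 (GFP+ replicate 2), 484 (GFP+ replicate 3), 321 (GFP+ replicate 4), 565 (bulk anterior), 206 (bulk dorsolateral) and 127 (bulk ventral), and after quantile normalization 1669. Another grouping of these 7 arrays, GFP+ replicate 1 with the bulk arrays, gave 1362 genes. Sorting, cell composition and tissue dissociation came together in this comparison, and p-values over bulk lobes are too small where arrays share an animal.

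The decreases rested on single arrays more than the increases did. Krt6b, Mmp12, Lpl, Calm4, Lce3a, Lce3f, Krtap13-1 and Itgax were each lost without any 1 of GFP+ replicates 2, 3 and 4, bulk dorsolateral and bulk ventral (adjusted p 0.057 to 0.18), and Mmp12 (0.073) and Lpl (0.066) also without bulk anterior. Aplnr was lost without bulk dorsolateral (0.066) or ventral (0.073), and Coch without bulk dorsolateral (0.054) or ventral (0.061). Pik3cd read 0.20 with the mean of its probe sets (adjusted p = 0.32).

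Of 19 immediate early genes 18 were higher and 0 lower in sorted cells (18 and 0 adjusted over the list alone), median 2.51, adjusted p = 1.0e-22. This was the list that passed with an estimated correlation too (adjusted p = 0.00287). Junb (3.36 ± 0.15), Jun (2.64 ± 0.14) and Nr4a1 (3.24 ± 0.18) were among them, and the list mean was 11.84 to 11.87 on the sorted arrays against 9.04 to 9.25 on the bulk ones. Tissue dissociation is known to induce these genes. Of 24 chemokines and cytokines 5 were higher (median 0.19, adjusted p = 0.149), with Cxcl1 (2.97 ± 0.44). Of 17 Wnt targets 1 was higher, Myc (2.33 ± 0.24), which is itself an immediate early response gene, median 0.92, adjusted p = 0.0235 (adjusted p = 0.693 with an estimated correlation). Without GFP+ replicate 1, 3 were higher and 1 lower (median 1.22, adjusted p = 0.0401), with Lef1 (1.69 ± 0.41) and Kremen1 (1.10 ± 0.21) higher and Cd44 (-0.71 ± 0.17) lower. Another probe set of Kremen1 read -0.48 with all sorted arrays. Of 12 luminal genes 2 were higher, Cldn4 (2.06 ± 0.26) and Elf3 (1.25 ± 0.21), and 0 lower (4 and 1 adjusted over the list alone), median 0.57, adjusted p = 0.0292 (adjusted p = 0.693 with an estimated correlation), and without GFP+ replicate 1, 6 were higher (median 0.73, adjusted p = 0.0474). Of 22 squamous genes 1 was lower, Krt6b, median -1.19, adjusted p = 0.00276 (adjusted p = 0.693 with an estimated correlation).

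Several lists of other cell types were lower in sorted cells. The macrophage list had a median of -2.99 (1 of 17 lower, adjusted p = 4.0e-05, and adjusted p = 0.693 with an estimated correlation), the fibroblast list -2.06 (3 of 15, 10 adjusted over the list alone, adjusted p = 3.9e-05, and adjusted p = 0.693 with an estimated correlation), the endothelial list -1.99 (2 of 13, adjusted p = 0.000183, and adjusted p = 0.693 with an estimated correlation) and the smooth muscle list -0.96 (4 of 12, 8 adjusted over the list alone, adjusted p = 0.000247, and adjusted p = 0.693 with an estimated correlation). The B and plasma cell list had a median of -1.62 (1 of 9, 6 adjusted over the list alone, adjusted p = 0.00496, and adjusted p = 0.693 with an estimated correlation), the neutrophil list -1.32 (0 of 14, adjusted p = 0.0235, and adjusted p = 0.693 with an estimated correlation) and the skeletal muscle list -2.18 (0 of 6, adjusted p = 0.0116, and adjusted p = 0.693 with an estimated correlation). Examples were Col1a1 (-2.95 ± 0.46), Kdr (-2.06 ± 0.34), Ms4a1 (-2.07 ± 0.39) and Ccr2 (-2.83 ± 0.44). Without GFP+ replicate 1, 16 of 17 macrophage genes (median -4.03), each of 13 endothelial genes (median -2.38) and 12 of 15 fibroblast genes (median -2.44) were lower. In that fit 7 of 9 B and plasma cell genes (median -2.01), 5 of 14 neutrophil genes (median -1.95) and 6 of 12 smooth muscle genes (median -1.04) were lower as well. GFP+ replicate 1 was known to have high leukocyte and endothelial and low luminal levels. Leaving it out thus favours lower values in lists of other cell types, and higher luminal ones, by construction. With all sorted arrays the T and NK list (median -0.18, adjusted p = 0.0551) did not pass, while Cd3g of that list was lower by itself (-2.79 ± 0.38). Without GFP+ replicate 1 the T and NK list (3 of 11 lower, median -0.41, adjusted p = 0.0191) and the transition list (3 of 11 lower, median -0.40, adjusted p = 0.0339) passed. Of the lists in that fit, the immediate early list alone passed with an estimated correlation (adjusted p = 0.022). The proliferation (median -0.15, adjusted p = 0.514), interferon (median -0.13, adjusted p = 0.804) and androgen lists (median -0.36, adjusted p = 0.0976) did not pass. Medians, means and tests differed in sign for the YAP (-0.27, 0.04, down), basal (-0.01, 0.12, up) and urothelium lists (-0.18, 0.02, down), none of which passed.

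Of the 11 lists that passed, the Wnt call was lost without GFP+ replicate 2 (adjusted p = 0.065), GFP+ replicate 3 (0.058) or bulk ventral (0.21), and after quantile normalization (0.094). The luminal call was lost without GFP+ replicate 3 (0.076) or bulk dorsolateral (0.097), and after quantile normalization (0.19). The neutrophil call was lost without GFP+ replicate 2 (0.25) or bulk dorsolateral (0.094). The squamous call was lost without bulk dorsolateral (median -0.67, adjusted p = 0.092), while the median was -2.04 without bulk anterior, and the skeletal muscle median was -1.09 without bulk dorsolateral. Of 34 list members named by the rule that passed limma's test, 12 passed in each fit without 1 array, Fosb, Junb, Jun, Nr4a1, Myc, Tgif1, Ccn1, Spink1, Cldn4, Cd3g, Il6 and Csf2. Losses were most frequent without bulk dorsolateral (20) and bulk ventral (20), with adjusted p up to 0.193. Neither Smad4 (0.02 ± 0.19) nor Apc (0.10) differed detectably (limma, adjusted p = 0.947 and 0.75), and 2 other Smad4 probe sets read -0.91 and -0.72.

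Genes that rose in bulk PtenApc against Pten tumours were set against the sorted cells. Of those 1871 genes, 37.8% were higher in sorted than in bulk PtenApc, compared with 52.3% of all genes tested. Of them, 71 were called higher and 118 lower in sorted cells. The share per sorted array was 49.9%, 43.0%, 33.5% and 34.6% (SD 7.73). Of the genes that fell, 50.9% were higher in sorted cells. Krt6b, Mmp12 and Calm4 were among those called lower. Without GFP+ replicate 1, 150 of the genes that rose were called higher and 529 lower, and the share was 36.6% against 58.1% of all genes. Of the genes that fell, 62.6% were higher in that fit, with 383 called higher and 151 lower, against 83 and 78 with all sorted arrays. The bulk PtenApc arrays enter both differences, which by itself lowers the share for genes that rose and raises it for genes that fell.

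Dorsolateral and ventral arrays of the same genotype, replicate number and age were compared to ask which transcripts mark a lobe. With limma, 0 genes passed, and 942 had an unadjusted p under 0.05. The fit takes a common lobe difference over all genotypes, so a difference in Pten tumours alone is averaged down. For 105 genes chosen as at least 2-fold higher in the ventral array of both Pten pairs, the medians were -1.38 and -1.60. They were -0.15 in PtenApc and 0.10 in PtenSmad4. The 0 thus does not show that lobes lack marker transcripts. The 5 smallest p-values, each with an adjusted p of 0.669, belonged to the Wnt modulator Dkk2 (1.60 ± 0.17), Nostrin (0.73 ± 0.09), Pcdhb20 (0.69 ± 0.09), Id3 (0.94 ± 0.12) and the prostate transcription factor Gata2 (1.46 ± 0.20). Without PtenSmad4 dorsolateral 1 gene passed, Car3 (3.55 ± 0.11, limma, adjusted p = 0.0104), which was named after its values were seen. As lists, 19 of 27 passed with the preset and 0 with the estimated correlation (adjusted p 0.501 to 0.525 for these). Examples of medians were 3.23 for seminal vesicle (adjusted p = 0.000897), 1.29 for skeletal muscle (adjusted p = 0.00167), 0.55 for neutrophil (adjusted p = 0.00028) and 0.54 for Wnt target genes (adjusted p = 3.9e-05). The skeletal muscle call was lost without PtenApc dorsolateral (adjusted p = 0.061). Without PtenApc ventral the seminal vesicle, neutrophil and Wnt medians were 1.84, 0.33 and 0.15, without PtenApc dorsolateral the Wnt median was 0.31, and without either Pten array of replicate 1 the neutrophil median was 0.95.

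The anterior lobe of the double deletions was compared with the mean of their dorsolateral and ventral lobes. With limma, 0 genes passed, and 819 had an unadjusted p under 0.05. Without PtenSmad4 anterior 27 passed. The smallest p-values were those of Aqp3 (-1.84 ± 0.19), Padi3 (-1.21 ± 0.13) and Clic3 (-0.86 ± 0.09), with adjusted p = 0.363, and of the cholesterol synthesis genes Mvd (-0.75 ± 0.09) and Hmgcs1 (-0.80 ± 0.11), with adjusted p = 0.426. As lists, 10 passed and 0 with an estimated correlation. Squamous genes were lower in the anterior lobe (median -1.47, 9 of 22 adjusted over the list alone, adjusted p = 1.4e-16) and so were basal genes (median -1.19, 6 of 11 adjusted over the list alone, adjusted p = 2.1e-07). Both had an adjusted p = 0.619 with an estimated correlation. Examples were Krt13 (-2.92 ± 0.53), Tgm1 (-1.54 ± 0.27) and Krt5 (-1.73 ± 0.35). The squamous median was -0.85 without PtenApc anterior and -2.24 without PtenSmad4 anterior, and the basal median -0.39 and -2.00. The Wnt, androgen, fibroblast and urothelium lists, which did not pass, differed in sign between median, mean or test.

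Whether dorsolateral and ventral lobes differed otherwise in the double deletions than in Pten tumours was tested on 8 arrays. With limma, 0 genes passed, and 1570 had an unadjusted p under 0.05. The smallest p-values were those of Spink5 (4.85 ± 0.18, adjusted p = 0.182), Crabp1 (5.43 ± 0.32), Bhlha15 (3.50 ± 0.21), Mecom (-2.39 ± 0.14) and the homeobox gene Hoxa9 (-2.13 ± 0.13, adjusted p = 0.201). Without any 1 array the count stayed at 0. As lists, 8 passed and 0 with an estimated correlation (adjusted p = 0.919 for each of the 8), with endothelial genes at a median of -0.75 (adjusted p = 8.7e-05). That median was -0.42 without either array of Pten replicate 2.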

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

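The tests of non-epithelial cells, of a mislabelled array, of lost squamous cells, of basal genes in sorted cells, of leukocyte numbers and of a single Pten tumour were chosen after the result was seen, as were the tests of single interaction arrays. Each group of 4 arrays was checked for 1 array far from the others, for named genes and gene lists. Of 218 such groups 9 had one, 6 of them GFP+ replicate 1, and chance alone gives about 1 in 20 groups.

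GFP+ replicate 1 stood apart from the other sorted arrays, with a luminal list mean of 11.44 on the log2 scale (12.02 to 12.08 in the others) and an endothelial list mean of 8.056 (5.495 to 5.771). An array of undissociated bulk tissue mislabelled as sorted is argued against. The immediate early list mean of GFP+ replicate 1 lay 2.61 above the highest bulk PtenApc array, as on the other sorted arrays. Dissociation is known to induce these genes, so cells dissociated but not sorted would read the same and stay open. Over genes, GFP+ replicate 1 was nearest to bulk PtenApc dorsolateral (SD of the difference 0.833). The SD was 0.888 to 0.984 against the other sorted arrays. RNA quality cannot be told apart by the rule set, since the 3' minus 5' difference lay outside the other sorted arrays by more than their SD for 1 of 2 control genes, Actb (0.32 against 0.80 to 1.06), and by less than it for Gapdh (-0.256 against -0.131 to 0.495). Both differences were lower than on the bulk arrays too (0.68 to 1.07 and -0.187 to -0.046). That is the opposite of a loss of 5' signal, so these 2 controls argue against more degraded RNA in this array. Leukocytes and stromal cells that passed the sort may be present, as in 8 of 8 leukocyte, stromal and adipocyte marker lists this array had the highest mean of the sorted arrays, with a macrophage mean of 10.50, but the lowest for skeletal muscle genes (5.16 against 5.33 to 5.59). The sort for GFP should remove such cells, and whether they carried GFP was not measured.

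Squamous genes had a median of -2.04 in sorted cells against the dorsolateral and ventral PtenApc lobes alone, while 1 of 22 was called lower against all 3 lobes and the list was not called without bulk dorsolateral (adjusted p = 0.092) or with an estimated correlation (0.693). Against the anterior lobe their median was 0.13 and against Pten tumours 0.57, so a loss of all squamous cells at the sort is neither shown nor excluded, and no GFP-negative fraction was used here to decide it. Whether sorted cells came mostly from the anterior lobe stays open, because the values point both ways. Over 146 genes higher in the anterior lobe, by a median of 1.54, sorted cells lay 1.01 above the dorsolateral and ventral lobes. This met the rule set beforehand. The value was 0.04 in Pten and 0.05 in PtenSmad4 tumours, and per sorted array 0.28, 1.15, 1.22 and 1.39. Against it stand basal genes, a check added after the result was seen. These were also low in the anterior PtenApc array (7.74, against 9.26 dorsolateral and 9.16 ventral) but read 8.69 to 9.04 in sorted cells. A share of cells that the sort changed in any lobe stays open as well.

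Interferon-stimulated genes were lower in bulk PtenApc tumours. Fewer leukocytes are argued against, because the lower of the macrophage and neutrophil list medians in the same comparison was 1.42, that is, higher in PtenApc. A single Pten tumour with high levels is argued against as the whole cause, since the median was -1.40 (quartiles -1.89 to -1.05) against Pten replicate 1 alone, and normalization likewise, with a median of -1.82 after quantile normalization. The list call was lost with an estimated correlation (adjusted p = 0.371). On the sorted PtenApc arrays, from mice of other ages than the bulk ones, the list means were 8.40, 8.09, 8.36 and 9.02. Bulk PtenApc arrays read 8.34 to 8.70 and Pten arrays 9.49 to 10.52, so the low level was not confined to the bulk PtenApc arrays. No sorted Pten cells were measured, so an effect of the sort on these means cannot be told apart. A difference of the bulk PtenApc arrays for reasons other than Apc was not tested otherwise and stays open beside an effect of the genotype.

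Other single values far from their group were, on the log2 scale, Pnliprp2 at 13.2 in GFP+ replicate 2 (11.51 to 11.73 in the others), Mvd at 6.811 in GFP+ replicate 3 (7.306 to 7.405) and Lif at 5.947 in Pten dorsolateral replicate 1 (6.692 to 6.842). In GFP+ replicate 1 they were Adh6a at 4.484 (5.372 to 5.523), Krt10 at 5.183 (6.42 to 6.663), Rttn at 5.134 (5.933 to 6.097) and Dkk2 at 9.588 (10.93 to 11.11).

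The difference between dorsolateral and ventral lobes was another one in the double deletions than in Pten tumours for 8 gene lists, by limma's camera on the interaction. The medians of the difference were -0.2006 for TGF-beta and BMP targets, -0.513 for basal, -1.676 for progenitor-like luminal, 1.039 for neutrophil, -0.5504 for macrophage, -0.7497 for endothelial, 0.3478 for immediate early and -0.6982 for interferon-stimulated genes. None held with an estimated correlation (adjusted p = 0.919 for each). Without the arrays of Pten replicate 1 the immediate early median was -0.0049 and the neutrophil call was lost (median 0.47), and without those of Pten replicate 2 the macrophage median was 0.13, the immediate early one 0.74, the neutrophil one 1.81, the endothelial one -0.42 and the interferon one -0.29. Without either PtenApc array the neutrophil (0.48) and macrophage calls (-0.32) were lost and the progenitor-like median was -0.84. Without either PtenSmad4 array the TGF-beta (-0.18), basal (-0.37) and interferon calls (-0.61) were lost and the neutrophil median was 1.72. The basal call was also lost without Pten replicate 2 (-0.32), the TGF-beta median was -0.12 without it and -0.41 without either PtenApc array, and the macrophage median was -1.14 without Pten replicate 1.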

How the results depend on the processing

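The settings with a Pten tumour of nearest age, with single arrays left out of gene lists, the interaction and the share of genes above bulk, and with gene lists over all 14 arrays were chosen after seeing the data. Quantile normalization moved the median of all genes by less than 0.1. Called lists and named genes mostly kept direction and side of the threshold. For PtenApc against Pten this held in 216 settings of lists and 367 of genes, with 36 and 23 calls lost. For PtenSmad4 against Pten it held in 122 and 369 (32 and 23 lost), for PtenApc against PtenSmad4 in 189 and 303 (35 and 64 lost) and for sorted against bulk cells in 90 and 220 (20 and 49 lost). Between lobes it held in 169 (57 lost) for dorsolateral against ventral and 94 (23 lost) for anterior lists, and in 54 (22 lost) for interaction lists.

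With an estimated correlation the numbers of lists called were 0, 0, 0, 1, 0, 0 and 0, against 18, 11, 16, 11, 19, 10 and 8, in the order PtenApc against Pten, PtenSmad4 against Pten, PtenApc against PtenSmad4, sorted against bulk, dorsolateral against ventral, anterior, and interaction. Genes within a list vary together across few arrays, and that widens the test by construction. Without 1 array the numbers of lists were 14 to 19, 7 to 13, 12 to 18, 8 to 15, 11 to 21, 9 to 12 and 11 to 13. The numbers of genes were 1885 to 4299, 306 to 2575, 675 to 2257, 127 to 3351, 0 to 1, 0 to 27 and 0 to 0, and fewer arrays give fewer degrees of freedom. With a replicate block (tumour as a random block, correlation -0.339) 6767, 5324 and 7561 genes were called in the 3 genotype comparisons. That correlation is negative, which shrinks errors between tumours by construction, and Apc in PtenSmad4 against Pten then passed at -0.15. That numbers tie lobes to 1 tumour is taken from the labels. It could be checked in Pten alone, where dorsolateral and ventral arrays of the same number and age were no more alike (r -0.07). All 14 arrays gave 1445, 837 and 608 genes, and 3338 for sorted against bulk cells. Pten replicate 2 alone gave 722 for PtenApc and Pten replicate 1 alone 526 for PtenSmad4, with fewer controls. Sorted against bulk gave 1669 after quantile normalization and 565 against dorsolateral and ventral arrays alone. The correlation of both deletions was 0.531 with the Pten replicates split the other way. The share of genes above bulk was 36.2 to 39.0% without 1 sorted array. The cause was not tested where none is named.

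Directions turned as follows, also for called lists. Apc in PtenApc against Pten was -0.022 with the mean of probe sets. In sorted against bulk cells Smad4 was -0.081 after quantile normalization, -0.54 with the mean of probe sets, -0.034 against dorsolateral and ventral arrays alone, and -0.085 (without bulk dorsolateral) to 0.19 (without bulk ventral) over single arrays left out, also negative without bulk anterior (-0.034) or GFP+ replicate 4 (-0.077). Apc was -0.18 with the mean of probe sets, and -0.014 (without GFP+ replicate 2) to 0.22 (without GFP+ replicate 1). Between dorsolateral and ventral arrays Apc was -0.00092 (without PtenApc ventral) to 0.056, and the fibroblast list -0.018 (without either array of Pten replicate 2) to 0.44. In the anterior comparison the TGF-beta list was -0.27 to 0.015 and the macrophage list -0.89 to 0.13, both highest without PtenApc anterior, and the proliferation list -0.82 to 0.062, highest without PtenSmad4 anterior. In the interaction the immediate early list was -0.0049 (without Pten replicate 1) to 0.74 and the macrophage list -1.14 to 0.13 (without Pten replicate 2). Apc there was -0.044 and Smad4 -0.22 at the lowest, without an array of PtenApc or of PtenSmad4, and Smad4 was 0.49 at the highest. The cause was not tested.

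Of lists not called, 9, 16, 11, 16, 8, 17 and 19 in the order above, the median changed sign in some setting for 3, 7, 5, 6, 5, 15 and 15, and 2, 3, 5, 7, 8, 11 and 16 were called in some setting. With the mean of all probe sets 8, 11, 7 and 21 called genes took the opposite sign in the first 4 comparisons. Planned settings for linear values were not run, since the values are log2. Genes near background, under a mean of 5.19, were left out of the main tests and entered in the setting without a filter.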

Other observations

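The tests of lobe genes and of splits without GFP+ replicate 1 were chosen after the result was seen, and Spink5, Crabp1 and Spink1 are named as those with the largest ventral excess over both Pten pairs. These genes, higher in the ventral array of both Pten pairs, were not so in the double deletions. Spink5, a protease inhibitor, read -4.46 and -4.39 in dorsolateral minus ventral arrays of Pten replicates 1 and 2, and 0.62 and 0.23 in PtenApc and PtenSmad4. Crabp1, a retinoic acid carrier, read -4.43 and -4.20 in Pten and 1.52 and 0.71 in the double deletions. Spink1 read -5.14 and -4.12 in Pten, and 0.07 and 0.30 in the double deletions.

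A hypothesis from these values is that the double deletions lost the lobe difference of these genes. Over 105 genes at least 2-fold higher in the ventral array of both Pten pairs, the median of dorsolateral minus ventral was -1.38 and -1.60 in Pten, and the double-deletion value farther from 0 was -0.15 (PtenApc), with 0.10 in PtenSmad4. The genes were chosen in Pten, which favours a smaller value elsewhere. Yet 208 genes chosen on Pten replicate 1 alone read -1.03 in replicate 2, and -0.05 in PtenApc and 0.11 in PtenSmad4. The 207 genes higher in the dorsolateral array of both Pten pairs read 1.60 and 1.62 in Pten, and -0.19 and 0.20 in the double deletions, where 86 (PtenApc) and 144 (PtenSmad4) kept their sign. By the same rule 20 genes were higher in the dorsolateral and 1 in the ventral array of both double deletions, and how many chance gives was not counted. With limma, 0 genes passed the interaction (1570 at an unadjusted p under 0.05), so the lost difference may hold. A dissection that mixed lobes could give the same differences, but not levels below both Pten lobes. Of these genes, Spink1, Adh6a, Cdcp3, Azgp1 and Slc9a2 were among the largest decreases of PtenApc against Pten tumours. Over all genes, dorsolateral and ventral arrays differed by an SD of 0.516 in PtenApc, 0.471 and 0.525 in the Pten pairs, and 0.233 in PtenSmad4. Mixing thus stays open mainly for PtenSmad4.

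Seminal vesicle genes varied by array. Their list mean was 11.37 and 11.54 in the anterior and dorsolateral PtenApc arrays, 8.39 and 9.91 in GFP+ replicates 3 and 4, 3.41 and 3.19 in GFP+ replicates 1 and 2, and 3.04 to 3.10 in PtenSmad4 arrays.

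The arrays were regrouped in the same group sizes and the fits repeated. For PtenApc against Pten and for PtenSmad4 against Pten, 1 of 35 splits gave as many genes as the real one (4094 with a highest other of 2, and 2518 with a highest other of 23), so chance can be excluded for a grouping of arrays. By replicate number and age in the labels the double deletion has 1 tumour and Pten 2, too few to exclude chance between tumours if the numbers stand for tumours. For PtenApc against PtenSmad4 the 10 splits are too few, with 2489 genes and a highest other of 41. For sorted against bulk cells 2 of 35 splits gave as many, 1068 genes with a highest other of 1362, so chance is not excluded. That split sets GFP+ replicate 1 with the 3 bulk arrays and points to a structure among the sorted arrays. Without that replicate the 10 splits are too few, with 3351 genes and a highest other of 1. For dorsolateral against ventral lobes the 8 swaps are too few, and 8 gave 0 genes like the real one.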
